A study of Mus musculus with 18 samples.

How the data were processed

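The 18 libraries were of polyA RNA from untreated cultured cells of mouse pancreatic tumour lines 1151 and 2838, in 6 groups of 3. Groups, replicate numbers, clones and batches were taken from the labels. The authors deposited one table of TPM values for 35642 gene symbols, made with Salmon against mm10, per the submitters' processing notes, which also name DESeq2. No versions of these tools, and no annotation, were given in the sources used here. TPM divides each estimate by transcript length and scales every library to 1000000, so a rise in a few abundant genes lowers all others and the read depth is lost. Columns summed to between 998353 and 998961 TPM. Because depth was unknown, no counting interval was given.

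From these values, log2(TPM + 1) was tested with limma 3.58.1 in R 4.3.3, with a trend in the variance prior and Benjamini-Hochberg adjustment, and a gene was called at an adjusted p under 0.05. Fold changes are on the log2(TPM + 1) scale, which understates changes of low genes. Genes needed 1 TPM in at least 3 libraries of a fit. Line 1151 was tested over its 6 libraries. In 2838 the clone was the unit of replication, so the main test compared 2 clone means with 2, and a second count asked for an adjusted p under 0.05 and one sign in all 4 pairs of a knockout-labelled and a wild-type-labelled clone. The difference of the effects was tested as an interaction on the 6 group means. The labels do not say that libraries of a group came from separate cultures, so p-values between libraries may measure technical spread only.

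In all, 34 gene lists of mitochondrial, epithelial, tumour and other cell type genes, 948 entries, were fixed before the data were examined. They were tested with camera at a preset correlation of 0.01 and at an estimated correlation, and with fry, adjusted over the lists of a comparison. The preset-correlation calls named in the text were all lost with an estimated correlation. That setting also takes its degrees of freedom from the few libraries or clone means of a fit. Calls could therefore be lost whatever the correlation. The mesenchymal call in 1151 was lost at an estimate of -0.0345, below the preset. The loss alone therefore does not show that correlation between genes produced the calls. Named genes were the 12 largest rises and 12 largest falls in each line among called genes whose arms did not overlap in any library, with a mean of at least 5 TPM in the higher arm and a symbol that is not a predicted or clone name. In 2838 each direction was filled from the all-pairs genes. In 1151, arms of 3 and 3 libraries separate by chance for 10% of genes. To these were added the uniporter genes, 11 markers of epithelial and mesenchymal state, and up to 4 called members of each list. Krt7, Cldn4, Cdh3, Tjp1, Fasn, Acaca, Acly and Tgfb1 in 1151, Tff1, Sprr1a, Sparc, Wnt5a, Gm10925, Gm29216 and Gm9797 in 2838, Lgals4, Col5a1, Cela1, Ptprc, Dcn, Lum and the Y-linked genes were chosen after their values were seen. Some genes that the rule names, and 1 of the lists, are not reported here.

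Gene positions, transcript lengths and GC content came from GENCODE M21 (mm10), matched by symbol for 97.8% of the genes tested. No pair of libraries held identical values throughout. Each fit was tested on simulated data with 200 changed genes, all well expressed in both lines. Scatter between groups was simulated in 2838 only, with one size for all genes, so a divergence of the 1151 populations was not simulated. The 1151 fit recovered 56%, 94%, 100% and 100% of log2 changes of 0.5, 1, 2 and 4, with 13 false calls of 188. The 2838 clone-mean fit recovered 2%, 38%, 98% and 100%, with 11 false calls of 130, and the all-pairs count 8%, 42%, 90% and 100%, with 7 of 127. The interaction fit recovered 0%, 0%, 14% and 96%, with 10 false calls of 65. The size of 4 was added after a first simulation in which the interaction fit recovered none of the smaller changes and all of its calls were false; false calls fell on genes that vary between 1151 libraries, a spread that fit does not see.

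Alternatives fixed before the data were examined were another pseudocount (0.1), no filter and a mean of at least 5 TPM, median-of-ratios scaling, quantile normalization, removal of mitochondrially encoded genes, no trend, a minimum log2 change of 1, a replicate block, other units of replication, and leaving out each library or clone. Added after seeing the data were lists of at least 5 tested genes, interaction calls that also pass the 18-library fit, clones left out of the list, gene and interaction results, and centring per chromosome.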

Results

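RNA was sequenced from 2 mouse pancreatic tumour cell lines, 1151 and 2838, derived from KPCY mice, a genetic model of pancreatic cancer with a yellow fluorescent reporter. The comparisons concern Mcu, the pore subunit of the mitochondrial calcium uniporter, and the series title names epithelial cell plasticity as its subject. Line 1151 had, per the labels, lost Mcu through Cre recombinase and was measured with an empty vector (labelled knockout) or with MCU put back (labelled re-expressing). Line 2838 was measured as 2 clones labelled wild type (15 and 22) and 2 clones labelled CRISPR knockout (17 and 42). The clones labelled wild type carried an empty vector, which the labels do not name for the clones labelled knockout. Each of the 6 groups had 3 libraries, 18 in all. Line 1151 was labelled batch 1 and line 2838 batch 2, so levels were tested only within a line. The deposited values were TPM, transcript abundances corrected for length and scaled to one total per library, which keep no record of depth, so the depth of each library was unknown. Between 10760 and 11507 genes reached 1 TPM in a library. The lowest number belonged to wild-type clone 22 replicate 3, which also had an upper quartile of 3.73 TPM against 7.54 and 7.45 TPM in the other libraries of its clone.

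Mcu RNA did not follow the labels in line 1151 or in 2838 clone 17. Mcu lies on chromosome 10 from 59446984 to 59616692 on the minus strand (mm10). In 1151 it stood at 15 ± 1.63 TPM in the cells labelled knockout and 14.3 ± 1.06 TPM in those labelled re-expressing (SD, n = 3 each), a log2 difference of 0.067 (SE 0.10, adjusted p = 0.581). In 2838 it was 75.2 ± 6.44 TPM in the clone labelled wild type 15, 83.3 ± 20.8 TPM in wild type 22 and 11.4 ± 0.888 TPM in the clone labelled knockout 42 (SD, n = 3 each). The clone labelled knockout 17 held 119 ± 4.79 TPM, above both clones labelled wild type in all 3 libraries. In 1151 the median log2 change of genes on chromosome 10 was 0.36, so Mcu lay below the median of its own chromosome. RNA from an edited gene can persist, and RNA from an introduced MCU may not be counted under the mouse gene, so these levels check the labels only in part. All directions below are those of the libraries as labelled. Of the other uniporter genes in 1151, Micu2 (log2 change -0.58, adjusted p = 9.04e-04) and Mcur1 (-0.33, adjusted p = 0.00944) were lower in the cells labelled knockout. Adjusted over the list alone, 0 of the 7 uniporter genes were higher and 2 lower. None of the 7 uniporter genes passed the clone-mean test in 2838.

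**Figure D1:**
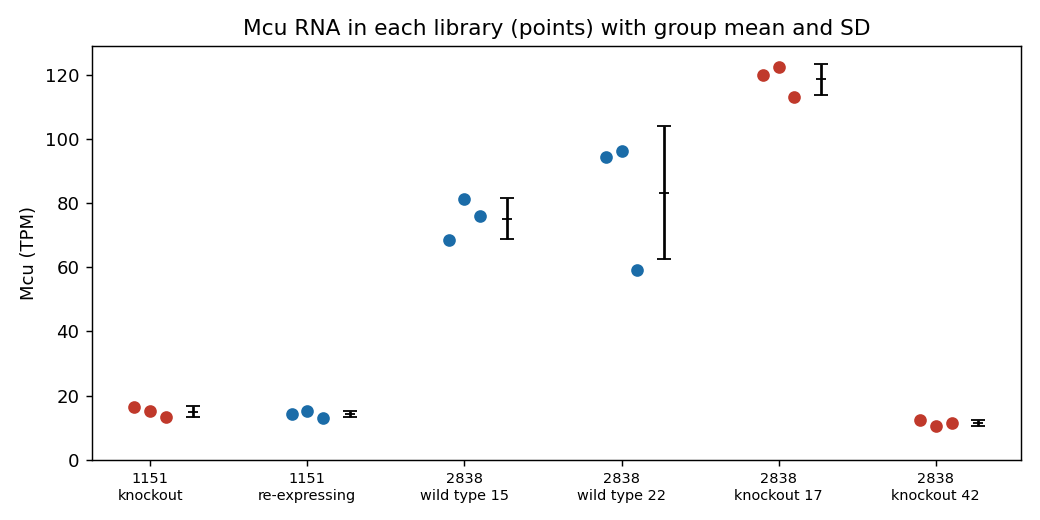
Mcu RNA in TPM in each of the 18 libraries (points; red for groups labelled knockout, blue for the others), with the mean and SD of each group of 3 beside them. The clone labelled knockout 17 lies highest, at 119 TPM, and the clone labelled knockout 42 lowest, at 11.4 TPM.

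The first comparison asked how the 1151 cells labelled knockout differed from those labelled re-expressing. Trefoil factors, small secreted proteins of mucous epithelia, were abundant in the re-expressing cells and nearly absent from those labelled knockout. Tff1 (chromosome 17, 31161395 to 31165277, minus strand) fell from 4261 ± 132 to 0.411 ± 0.356 TPM (SD, n = 3 each; log2 change -11.60, SE 0.18, adjusted p = 1.47e-07). Tff2 and Tff3 were listed at 0 in the 3 libraries labelled knockout and stood at 513 ± 27.1 and 244 ± 34.3 TPM in the others. In the opposite direction, Tm4sf4, a membrane protein of the transmembrane 4 L6 family, rose from 0.147 ± 0.0897 to 289 ± 18.9 TPM and Cav1, the caveolar coat protein caveolin-1, from 11.1 ± 1.64 to 367 ± 22 TPM. Thbs1, the matrix protein thrombospondin-1, rose from 0.137 ± 0.0637 to 30.2 ± 1.65 TPM.

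Among genes tested, 3958 were higher and 3140 lower in the cells labelled knockout, of 11630, and 874 and 697 of these changed by a log2 of at least 1. The excess of rises depended on the scaling: 3603 were higher and 3474 lower with quantile normalization, 3506 were higher and 3613 lower with median-of-ratios scaling, and 3363 were higher and 3374 lower after centring each library per chromosome. Besides the genes above, the largest rises were in Crip1 (log2 change 7.17), the chemokine Cxcl12 (5.51), Sema4f (5.45), Uchl1 (5.42), Hs6st2 (5.31) and Mapk13 (4.54). Fundc2, Fgf13 and Npw were listed at 0 in the 3 re-expressing libraries and stood at 32.5, 28.3 and 24.4 TPM in those labelled knockout. Further falls were seen in Plac8 (log2 change -5.45), the water channel Aqp1 (-5.47), Fxyd3 (-5.23), Syt8 (-5.14), the retinol-binding protein Rbp2 (-5.03) and Spink4 (-4.99). Sprr2a2 (-5.59), Prl2c2 (-5.10) and Prl2c3 (-4.78) also fell, but each has close paralogs, so their separate values are uncertain.

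Genes of the classical subtype of pancreatic cancer fell as a list in the 1151 cells labelled knockout. Of 20 members tested, 14 fell, 3 rose and 3 did not pass (median log2 change -1.24, camera adjusted p = 1.07e-05; adjusted p = 0.316 with an estimated correlation). Ctse, the gastric protease cathepsin E, fell from 141 to 5.75 TPM and Plac8 from 1281 to 28.4 TPM. The list of the basal-like subtype was not called in 1151, with 5 members higher and 3 lower of 9 (camera adjusted p = 0.748). Of 32 genes of cholesterol and fatty acid synthesis, 22 fell and 5 rose (median -0.62, adjusted p = 1.09e-04; adjusted p = 0.475 with an estimated correlation). Examples were the desaturase Scd1 (log2 change -1.66), Tm7sf2 (-1.67) and Insig1 (-1.05), which fell. The enzymes of fatty acid synthesis Fasn (1.11), Acaca (0.80) and Acly (0.55) rose. Of 75 nuclear genes of oxidative phosphorylation, 33 fell and 9 rose (median -0.29, adjusted p = 0.0113; adjusted p = 0.652 with an estimated correlation). Cox4i1 (-0.59) and Cox7b (-0.73) were among those that fell and Ndufa9 (0.49) among those that rose.

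Matrix and YAP target genes rose. Of 22 targets of the coactivator YAP, 20 rose and 0 fell (median 0.78, adjusted p = 3.51e-06; adjusted p = 0.316 with an estimated correlation), with Ccn1 at 165 ± 9.88 against 17.4 ± 0.571 TPM and Ankrd1 at 406 ± 15.6 against 67.2 ± 3.09 TPM. Of 25 collagen and matrix genes, 19 rose and 3 fell (median 0.88, adjusted p = 4.97e-04; adjusted p = 0.316 with an estimated correlation), among them Fbln2 (log2 change 2.95) and Tnc (2.33). Of 21 mesenchymal genes, 11 rose and 3 fell (median 0.89, adjusted p = 0.0272; adjusted p = 0.316 with an estimated correlation). Fn1, encoding fibronectin, stood at 88.3 ± 5.43 against 12.6 ± 0.669 TPM and Cdh2, N-cadherin, at 149.8 ± 7.03 against 35.5 ± 0.675 TPM. Vim, encoding vimentin, was 1824 ± 69.7 against 1847 ± 129 TPM and did not pass (adjusted p = 0.874).

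The epithelial list as a whole was not called by camera in 1151 (adjusted p = 0.537), with 11 members higher and 13 lower of 27. Krt19, a ductal keratin, fell from 826 ± 36.5 to 385 ± 4.67 TPM, and Cdh1, E-cadherin, fell from 230.0 ± 7.57 to 167 ± 13.7 TPM. Others rose: Krt7, a keratin of simple epithelia (log2 change 2.55), Cldn4, the tight junction protein claudin-4 (2.49), Cdh3, P-cadherin (1.26), and Tjp1 (1.12). Epcam did not pass the filter on low values. Transcription factors of the epithelial-mesenchymal transition were likewise not called by camera as a list (adjusted p = 0.0789), while Zeb1 (log2 change 0.67), Zeb2 (1.02), Snai2 (0.90) and Snai1 (1.07) each rose. Twist1 stood at 2.05 ± 0.436 TPM and was listed at 0 in the re-expressing libraries. Genes of S phase (22 higher, 4 lower of 39, adjusted p = 0.0147; adjusted p = 0.316 with an estimated correlation) included Mcm2 (0.91) and Rrm1 (0.69). Genes of TGF-beta signalling (13 higher, 2 lower of 22, camera adjusted p = 0.0464, and 0.316 with an estimated correlation) included Bmp2 (3.16) and Id3 (1.64). Among the 2 lower was the ligand Tgfb1 (-0.95). Genes of G2 and M phase (17 higher, 4 lower of 40, adjusted p = 0.0464; adjusted p = 0.681 with an estimated correlation) included Top2a (0.91). Adjusted over the list alone, counts differed by 1 gene for the classical (4 and 14 higher and lower), collagen (19 and 4), mesenchymal (12 and 3), TGF-beta (14 and 2) and oxidative phosphorylation lists (8 and 33). The calls of the TGF-beta and G2 and M phase lists were lost without knockout-labelled replicate 2 or any of the 3 re-expressing libraries, and the latter also under the scaling alternatives. By fry, which tests whether the genes of a list move one way on balance without comparing them with other genes, 29 of 32 lists passed in 1151. Among them were lists not called by camera, such as the epithelial list (adjusted p = 0.0012) and the transition factors (adjusted p = 8.70e-04).

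The 1151 test measures the spread between 3 libraries of one knockout population and 3 of one re-expressing population, and nothing in the labels says that the libraries came from separate derivations. With the spread between the 2838 clones in place of that between libraries, 268 genes were called instead of 7098, and the fit of all 18 libraries called 4562. The fit that gave 268 works on the 6 group means, with fewer values for its error, and on genes filtered over all 18 libraries. Its lower number is therefore not due to the spread of the clones alone. The change was also uneven across the genome: the median log2 change was 0.52 on chromosome 19, 0.46 on chromosome 15 and -0.29 on chromosome 8.

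**Figure D2:**
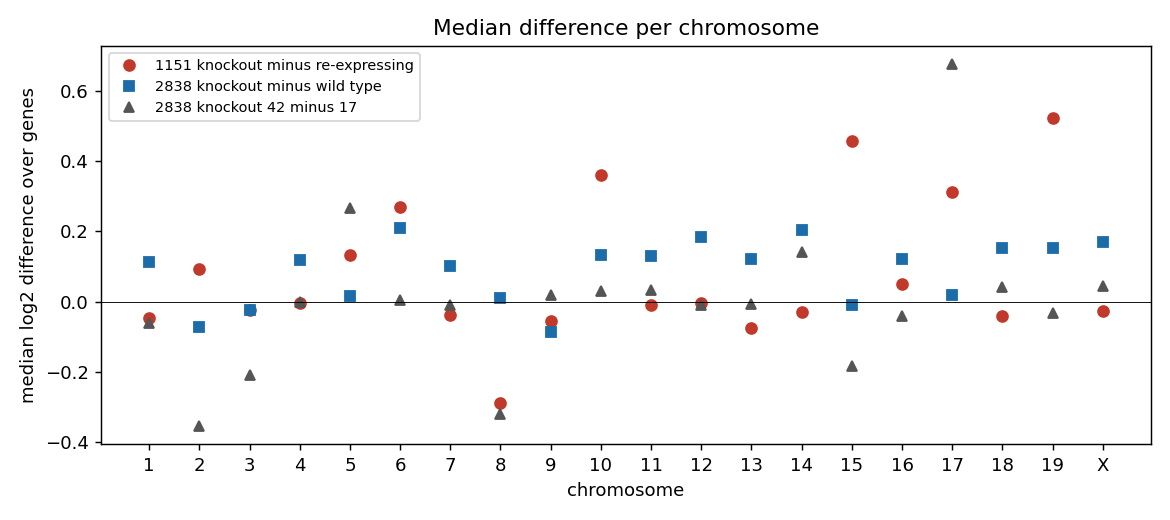
Median log2 difference over protein-coding genes on each chromosome, for the 1151 comparison (red circles), the 2838 comparison (blue squares) and the clones labelled knockout 42 and 17 against each other (grey triangles). The 1151 medians reach 0.52 on chromosome 19, and the clones labelled knockout differ by 0.68 on chromosome 17.

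The second comparison set the 2838 clones labelled knockout against those labelled wild type. Anxa6, a calcium-dependent membrane-binding annexin (chromosome 11, 54979108 to 55033445, minus strand), was 51.1 ± 6.89 and 52.8 ± 8.52 TPM in the clones labelled wild type 15 and 22 and 15.5 ± 1.21 and 14 ± 1.71 TPM in the clones labelled knockout 17 and 42 (SD, n = 3 each; log2 change -1.74, SE 0.23, limma adjusted p = 0.0355). Cp, the plasma copper protein ceruloplasmin, fell with a log2 change of -1.93 (adjusted p = 0.0355). Echdc2 stood at 16.1 and 15.6 TPM in the clones labelled wild type, was listed at 0 in the 3 libraries of clone 17 and stood at 1.09 TPM in clone 42 (adjusted p = 0.0119). Prl2c3 (log2 change 2.75, adjusted p = 0.00304) and Prl2c2 (2.03, adjusted p = 0.00526) rose, with the uncertainty between paralogs noted above. On clone means, 3 genes were higher and 6 lower of 11795, and 662 genes had an unadjusted p under 0.05 (limma). With no difference at all, a share of about 0.05 of the genes tested would have such a p. The other splits of the 4 clones gave 656 and 393 such genes, with 0 calls in each. The unadjusted number thus hardly set the labelled split apart from 1 of them. Of the 9 calls of the labelled split, 6 also changed one way in all 4 clone pairs. The calls include predicted genes whose arms overlapped between libraries: Gm10925 (-5.20), Gm29216 (-4.70) and Gm9797 (1.80). With quantile normalization 2 were higher and 2 lower, and with mitochondrial genes removed 3 and 10. The count was 0 (748 at an unadjusted p under 0.05, limma) without wild-type clone 22 replicate 3, 14 and 24 without replicates 1 and 2 of that clone, 5 without clone 15 replicate 2 or clone 17 replicate 3, and 4 without clone 42 replicate 3. Without clone 15 or clone 22 it was 0 (333 and 373 at an unadjusted p under 0.05), and without clone 17 or clone 42 it was 398 and 267.

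Asking that each clone labelled knockout differ from each clone labelled wild type gave 58 genes higher and 61 lower, and 61 and 109 after centring each library per chromosome. Among those higher were Gkn2, a gastrokine, at 18 ± 1.66 and 43 ± 4.99 TPM in clones 17 and 42 against 7.93 ± 3.35 and 2.09 ± 0.476 TPM in clones 15 and 22, the related Gkn1 (clone-mean log2 change 2.26), Tff1 (1.49) and Mucl3 (3.07). The basal keratin Krt14 (2.26), Fgfbp1 (2.08), Cd55 (1.58), Bcas1 (1.85), Grk5 (2.00), Lrrc26 (1.68) and Sprr2a2 (1.90) were also higher. Those lower included Fn1 at 29.7 ± 2.82 and 17.5 ± 4.92 TPM in clones 17 and 42 against 193 ± 13 and 96.5 ± 36.4 TPM in clones 15 and 22, the complement protein C3 (-2.99), transferrin Trf (-2.70), haptoglobin Hp (-2.50), Gc (-2.37), Wipf1 (-2.40), Cyp21a1 (-2.56) and Nkx2-3 (-2.37). None of these passed the clone-mean test, where the adjusted p was 0.0516 for Fn1 and 0.165 for Tff1. Without wild-type clone 22 replicate 3 the number was 457, without clone 17 replicate 1, 2 or 3 it was 65, 65 and 72, and without clone 42 replicate 1 or 2 it was 78. Arms that do not overlap in any library, which the named genes also had to show, arise by chance for 0.216% of genes with 6 independent libraries against 6, and for more where libraries of one clone resemble each other, as 2 clones fall on one side of the other 2 in 1 of 3 splits at most.

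In gene lists, epithelial genes were higher in the 2838 clones labelled knockout (23 of 26 positive, median 0.33, adjusted p = 0.00107; adjusted p = 0.617 with an estimated correlation). The same held for basal-like subtype genes (11 of 11 positive, median 0.66, adjusted p = 3.41e-06; adjusted p = 0.535 with an estimated correlation), whose members here include the cornified envelope gene Sprr1a (1.15). Classical subtype genes were higher too (18 of 22 positive, median 0.30, adjusted p = 0.00698; adjusted p = 0.535 with an estimated correlation). Collagen and matrix genes (11 of 27 positive, median -0.17, adjusted p = 0.0053; adjusted p = 0.535 with an estimated correlation) and mesenchymal genes (10 of 21 positive, median -0.067, adjusted p = 0.0174; adjusted p = 0.535 with an estimated correlation) were lower. Of the mesenchymal genes, Fn1 (-2.51), Sparc (-1.11) and Wnt5a (-1.03) had the most negative log2 changes. No member of any list passed the clone-mean test, and fry called 0 of 33 lists (lowest adjusted p = 0.465). Lysosome and autophagy genes (9 of 27 positive, adjusted p = 0.0174; 0.817 as the adjusted p with an estimated correlation), transition factors (3 of 7 positive, 0.0312; 0.817), inflammatory genes (11 of 25 positive, 0.041; 0.817) and TGF-beta genes (9 of 24 positive, 0.041; 0.817) were lower by the same tests. Targets of p53 (18 of 25 positive, 0.041 and 0.535 in the same order) were higher. Over all 11795 genes the median log2 change was 0.075, so most genes were positive and the counts of positive members carry this offset. Without wild-type clone 22 replicate 3 that median was -0.019. Adjusted over the list alone, basal-like genes had 2 and 0 members higher and lower, classical genes 4 and 0, collagens 1 and 0, mesenchymal genes 0 and 1, inflammatory genes 2 and 4 and transition factors 0 and 1. Without wild-type clone 22 replicate 3 the call of the inflammatory list was lost, and the call of the classical list was lost with no filter on low values.

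**Figure D3:**
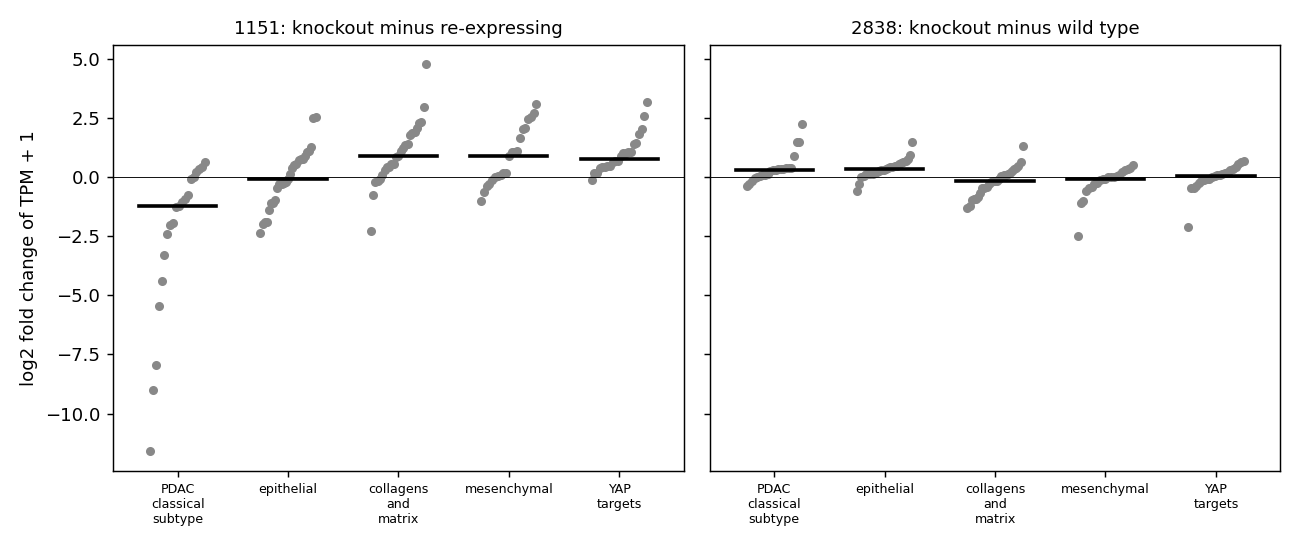
Log2 fold change of TPM + 1 of each tested member of 5 gene lists (points) with the list's median (bar), in 1151 (left) and 2838 (right), as labelled knockout minus the other arm. The median of the classical subtype list is -1.24 in 1151 and 0.30 in 2838.

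The third comparison asked whether the lines changed alike. Among 11081 genes tested in both, 10 rose and 15 fell in both lines by the all-pairs count, against 17.0 and 13.3 for independent lists (Fisher's exact test, two-sided p = 0.0374 and 0.629; adjusted over 8 such tests 0.129 and 0.718). Another 33 genes were lower in 1151 and higher in 2838, against 13.8 for independent lists (p = 1.98e-08, Fisher's exact test; adjusted p = 1.59e-07), among them Tff1, Ctse, Gkn2, Lgals4, Mucl3 and Sprr1a. The reverse held for 23 genes against 16.3 (Fisher's exact test, p = 0.0484, adjusted p = 0.129), among them Fn1, Anxa6, Ccl2, Csf1 and Col5a1. Genes are not independent replicates, so these p-values are too small by an unknown amount. Across genes the effects of the lines had a Pearson r of -0.131 and a Spearman rho of -0.0672. The other splits of the 4 clones, which set 1 clone labelled knockout and 1 labelled wild type against the rest, gave r of -0.0211 and -0.0869 and rho of -0.0155 and -0.158. Their signs are arbitrary, and 1 of them had a rho larger in size than the labelled split. The r was -0.0599 without clone 17 and -0.0786 without clone 15. The count of genes changed in opposite ways was 56, and 13 at a log2 change of at least 1. It was 28, 27 and 31 without clone 17 replicates 1, 2 and 3, 36 without clone 42 replicate 1 or 2, and 218 without wild-type clone 22 replicate 3. With clones 22, 17 and 42 left out in turn it was 535, 146 and 115, and with quantile normalization 98. By clone-mean calls, Echdc2 alone changed alike, falling in both. The count of genes changed alike was 25, and it was 106 without wild-type clone 22 replicate 3, 10, 11 and 11 without clone 17 replicates 1, 2 and 3, and 12, 14 and 15 without those of clone 42.

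The size of the change differed between the lines, as a test of the difference itself, for 82 genes higher and 55 lower (1151 effect minus 2838 effect; 12458 tested). Of these 137 genes, 95 did not pass the filter on low values in 2838, so that their difference restates the change in 1151 with an error from clones that hardly express the gene, and 42 were tested in both lines. Centred per chromosome, 131 genes were higher and 142 lower. For Tff1 the difference was -13.09 (adjusted p = 0.0337), for Ctse -5.26 (adjusted p = 0.0363), for Ccn1 3.54 (adjusted p = 0.0355) and for Csf1 4.64 (adjusted p = 0.0355). Fn1 went opposite ways in the lines, but its difference of 5.22 did not pass (adjusted p = 0.111). This fit takes its error from the 2838 clones alone. On simulated data it recovered 0% of differences of a log2 of 1 and 14% of those of 2, and 10 of its 65 calls were false. Those data held clone scatter of one size for all genes and none between the 1151 populations. Their changed genes were well expressed in both lines. The false-call rates may therefore not hold for the 95 genes above or where the 1151 populations diverged. Requiring the 18-library fit, which alone called 4190 genes, to call the gene with one sign kept 131 of the 137 genes. That left 2 false calls of 57 in the simulation. The count was 0 with any of the 4 clones left out, which leaves fewer clones for the error, and 0 without a trend in the variance prior (1723 at an unadjusted p under 0.05, limma). It was 4, 4 and 51 without knockout-labelled 1151 replicates 1, 2 and 3, 60, 9 and 73 without the re-expressing ones, and 78 without wild-type clone 22 replicate 1.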

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

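Of the tests in this part, those centring values per chromosome were set after the chromosome medians but before the centred values were seen, and the other tests of explanations were chosen only after the result was seen. The items here are genes and lists whose change differed between the lines by the interaction test, as 1151 effect minus 2838 effect on the log2 scale. Higher in the 1151 difference were Tm4sf4 (7.87), Hs6st2 (5.65), Cxcl12 (5.51), Sema4f (5.41), Fundc2 (5.06), Npw (5.05), Csf1 (4.64), Fgf13 (4.47), Anxa6 (3.58), Ccn1 (3.54), Fbln2 (3.24), Kdr (2.41) and Tnc (2.33). Lower were Tff1 (-13.09), Prl2c3 (-7.53), Sprr2a2 (-7.49), Prl2c2 (-7.13), Syt8 (-6.17), Fxyd3 (-6.06), Plac8 (-5.72), Ctse (-5.26), Spink4 (-5.22), Cdh5 (-2.56) and Tnfaip2 (-2.22). Each of these genes also passed the 18-library fit. Cdh5, Cxcl12, Kdr, Npw, Sema4f, Spink4 and Tnc did not pass the filter on low values in 2838, so their differences restate the change in 1151. Differences of genes near 0 in a group, among them Fundc2, Fgf13 and Npw, which were listed at 0 in the 1151 re-expressing libraries, depend on the pseudocount.

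As lists, the median difference was -1.34 for classical subtype genes, -0.70 for cholesterol and fatty acid synthesis and -0.30 for nuclear oxidative phosphorylation genes. It was 0.97 for YAP targets, 0.97 for mesenchymal genes, 0.92 for collagens and matrix, 0.86 for TGF-beta signalling, 0.81 for inflammatory genes, 0.79 for transition factors and 0.37 for proteases. With an estimated correlation none was called (lowest adjusted p = 0.628). By fry only the fibroblast list, with 4 members tested, passed (1 of 33 lists, adjusted p = 0.0426).

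The classical subtype list had medians of opposite sign in the lines, -1.24 in 1151 and 0.30 in 2838. No member passed the clone-mean test in 2838, and not every member differed in sign: Tff2 was negative in both (-9.01 and -0.29). Shifts of whole chromosomes were too small to be the whole cause of the fall in 1151, where the lowest chromosome median was -0.29. Centring each library per chromosome could therefore not have removed the list's difference, and its outcome adds no separate evidence. It left the median difference at -1.40 against -1.34 before, with medians of -1.50 in 1151 and 0.20 in 2838. Wild-type clone 22 replicate 3 is argued against as the whole cause of the rise in 2838, where the list's median was 0.21 without it against 0.30 and still called at the preset correlation, though not with an estimated correlation even with all libraries. An exchange of the 1151 labels stays open: Mcu RNA differed by a log2 of 0.067, which cannot be told apart from no difference, and an introduced MCU may not be counted. The median change on its chromosome 10 was 0.36. Mcu lay below that median but within the scatter of that chromosome's genes (median absolute deviation 0.53), which does not decide the matter. Divergence of the 1151 populations for reasons other than Mcu, and a real difference between lines, stay open as untested, with line and batch confounded.

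Many genes differed in 1151 and the medians of whole chromosomes differed as well. The SD of the 20 chromosome medians was 0.204, above the highest of 1000 shuffles of genes over chromosomes (0.0471, permutation p = 0.001, the smallest they can give). In 2838 the SD also exceeded its shuffles, at 0.0904 against 0.0212 for the labelled comparison. It was 0.0654 against 0.0280 between the clones labelled wild type and 0.214 against 0.0302 between those labelled knockout. The shuffles treat genes as independent, so exceeding them does not set 1151 apart. A difference in chromosome content between the 1151 populations is a candidate explanation for the 1151 shifts, and copy number was not measured. After centring per chromosome 6737 genes were called against 7098 before, with 5992 called in both with the same sign. The median shift of a gene's own chromosome therefore does not account for most calls. That outcome was likely beforehand, as many medians lay near 0 (-0.0037 on chromosome 4, -0.010 on chromosome 11). Effects of altered chromosome content on genes elsewhere, and changes in parts of chromosomes, were not tested. Other splits of the 6 libraries gave at most 1 gene. Each of them mixes the 2 populations within an arm, so their difference enters the spread and few calls follow whatever its cause. The contrast therefore says nothing about the cause, and 10 splits are too few for a share under 0.05 (1 of 10 gave as many). For the all-pairs count in 2838 the labelled split gave 119 genes and the highest other split 32, with 3 splits also too few (1 of 3 gave as many).

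Wild-type clone 22 replicate 3 stood apart from the other libraries of its clone. Its deviation from them fell with transcript length (Spearman rho across 9556 genes -0.703, against -0.309 to 0.373 for libraries outside that clone; genes are not independent replicates). The median deviation was -1.22 in the longest tertile of transcripts and 0.010 in the shortest. This is consistent with a loss of long transcripts in that library, such as RNA degradation would give. No biological explanation was tested, since the design names no difference between libraries of one clone.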

How the results depend on the processing

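Tests centring values per chromosome, those leaving a clone out of the interaction, list and gene results, the minimum list size and the requirement of a second fit were chosen after the data were seen. Among single results, no called 1151 gene named in the text changed direction under any alternative, with Tgfb1 not checked. The values below moved by more than 1.5 times, and their causes were not tested unless fewer libraries or genes are the cause by construction. With a pseudocount of 0.1, 0 genes changed alike by clone means (main value 1). With no filter, 2838 clone means gave 0 (978 at an unadjusted p under 0.05, limma), changed alike by clone means 0 and the difference between lines 1220. With a mean of at least 5 TPM, 16 genes changed alike. Median-of-ratios scaling gave 3 by clone means, 193 by all pairs, 49 alike and 0 alike by clone means, and quantile normalization 4, 215, 46 and 0, with 211 for the difference. Removing mitochondrial genes gave 2 alike by clone means. With no trend, clone means gave 4 and the difference 0 (1723 at an unadjusted p under 0.05, limma). At a log2 change of at least 1, 1151 gave 1571, all pairs 44, alike 4, changed in opposite ways 13 (main value 56) and alike by clone means 0.

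Without clone 15, clone means gave 0, all pairs 191, alike 49, alike by clone means 0 and the difference 0. Without clone 22 these were 0, 1303, 312, 0 and 0, without clone 17 398, 436, 126, 118 and 0, and without clone 42 267, 244, 52, 54 and 0. The differences of 0 had 1149, 1295, 1789 and 1891 genes at an unadjusted p under 0.05 (limma), in that order. With a clone left out 1 arm holds a single clone, so what follows rests on that clone, for results not called with all clones. For 2838 Tff2 the log2 change was -0.29 with all clones, 1.14 without clone 17 and -1.72 without clone 42. The medians of the G2 and M phase list were 0.16, 0.47 and -0.074 in that order, and of the difference between lines of the integrated stress response list 0.34, 0.95 and -0.53. For 3 lists the test with all clones pointed down beside a positive median, and turned up without that median changing sign. They were the oxidative phosphorylation list (median 0.074 with all clones, 0.21 without clone 22, 0.14 without only replicate 3 of that clone, -0.093 without clone 15), the S phase list (0.087, 0.51 without clone 17, -0.39 without clone 42) and the 2838 integrated stress response list (0.11, 0.74 without clone 42, -0.59 without clone 17). All 18 libraries in one fit gave 4562 genes in 1151, and the spread of the 2838 clones 268. For 2838, 12 libraries as 6 against 6 gave 431, clone as a random effect 118, and 4 clone groups 1155. The difference from 18 libraries was 4190. Centred per chromosome, clone means gave 3, alike 43, alike by clone means 0 and the difference 273.

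Leaving out each library in turn gave 5925 to 6993 genes in 1151, 0 to 24 by clone means, 65 to 457 by all pairs, 10 to 106 alike, 0 to 5 alike by clone means and 4 to 158 for the difference. Same-numbered 1151 libraries deviated from their group means with correlations of -0.146 to -0.0266, and those of 2838 with -0.152 to 0.19, so replicate numbers did not pair the libraries. With the replicate block 1151 gave 6672 genes, all pairs 100 and the 4 clone groups 964. Depth is not recorded in TPM, so what it limits is unknown.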

Other observations

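The gene lists tested in this part were fixed before the data were examined, and its values of chromosomes and single genes were chosen after they were seen. The clones labelled knockout also differed from each other by whole chromosomes: clone 42 minus clone 17 had a median log2 difference of 0.68 on chromosome 17 (89.8% of 590 genes higher), -0.36 on chromosome 2, -0.32 on chromosome 8 and 0.27 on chromosome 5. Of genes on the Y chromosome, Ddx3y stood at 21.6 and 24.8 TPM in the 1151 groups and Eif2s3y at 49.3 and 54.4 TPM, while both were listed at 0 in each 2838 group, with line and batch confounded.

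Most markers of other cell types were near 0. Of 21 acinar markers 1 was tested in 2838 and none in 1151, and that list's call in 2838 (adjusted p = 0.0174) is the value of Cela1 alone and was lost, among others, without wild-type clone 22 replicate 3. No endocrine marker was tested. Of 21 immune markers 2 were tested, with Cd14 at 31.1 and 67.9 TPM in the 1151 groups and the list not called (adjusted p = 0.537). Of 13 fibroblast markers 3 were tested in 1151 (list adjusted p = 0.393), led by Cxcl12, and of 12 endothelial markers 3 (adjusted p = 0.562), among which Kdr was higher and Flt1 and Cdh5 lower in the cells labelled knockout. Dcn, Lum and Ptprc stayed below 0.2 TPM in every group.

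The 13 mitochondrially encoded genes were not called by camera as a list in 1151 (adjusted p = 0.782) or 2838 (0.0613). Neither were, in 1151 and 2838 in turn, glycolysis (adjusted p = 0.53 and 0.846), the citric acid cycle (0.736 and 0.497), mitochondrial calcium and permeability (0.777 and 0.464), the uniporter complex (0.628 and 0.73) and calcium handling of the ER and plasma membrane (0.893 and 0.394). The same was true of the mitochondrial unfolded protein response (0.405 and 0.582), mitochondrial biogenesis (0.609 and 0.366), the oxidative stress response (0.078 and 0.497), the integrated stress response (0.246 and 0.925), hypoxia (0.561 and 0.846) and the interferon response (0.949 and 0.788). Camera tests a net shift in one direction, so members of such lists may still change both ways. Of 20 genes of ER and plasma membrane calcium handling, 10 were higher and 6 lower in 1151. Among all genes tested there, 61.0% were called. The median, mean and test of a list differed in sign, in lists that were not called, for 5 lists in 1151 and 7 in 2838.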
